A study of Mus musculus with 2 samples.

How the data were processed

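Single-cell RNA sequencing was carried out on cells sorted from the lateral subventricular zone, the adult neural stem cell niche beside the lateral ventricles, of male C57BL/6 mice. One age group was 2 months old, with tissue of 4 mice pooled, and the other 22 months old, with tissue of 8 mice pooled. Cells were sorted for GLAST, a glutamate transporter on radial glia-like stem cells and astrocytes. Cells carrying O4 (an oligodendrocyte lineage antigen), Ter119 (erythroid) or CD45 (leukocyte) were excluded. Per the labels, 8000 sort events per library entered the Chromium droplet workflow. There was 1 library per age.

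The deposited matrix held raw whole-number UMI counts per gene and barcode, with no normalization. A UMI is a molecular tag that lets each captured transcript be counted once. The submitters' processing notes name Cell Ranger 2.0.0 and the genome builds GRCm38.p3 and mm10, without saying what role each build had. How cells were called, how both libraries were merged and whether reads were subsampled to equal depth at merging are not given in the sources used here. Both libraries shared 1 matrix, in which each barcode ended in a library number. No label tied that number to an age. Values are therefore given for library 1 and library 2, and no comparison of young with old was made, nor was an age inferred from any value.

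The matrix had 3937 barcodes and 27998 genes, of which 18470 had a UMI. Library 1 had 1849 barcodes and 10440891 UMIs, with a median of 4463 UMIs and 1980 genes per barcode. Library 2 had 2088 barcodes and 13330251 UMIs, with a median of 5763 UMIs and 2355.5 genes per barcode. Barcodes with at least 500 genes and at most 10% of UMIs from mitochondrial genes were kept. This removed 9 barcodes of library 1 and 13 of library 2, all for the mitochondrial share. Doublets were called by Scrublet in each library with an expected rate of 1.5%, which marked 15 barcodes (0.811%) of library 1 and 11 (0.527%) of library 2. The 1825 and 2064 cells that remained were analysed.

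Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were taken from genes seen in at least 5 cells and outside the gene lists, so that list members did not shape the clusters. Scaled values entered 30 principal components, and a shared-neighbour graph of 15 neighbours was partitioned by the Leiden method at resolution 1, which gave 18 clusters. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, scipy 1.17.1, sklearn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, with seed 1.

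A cluster was named after a cell class from 163 fixed markers of 14 classes. The name went to the class with the highest mean log2 fold of its markers over all other cells, with 10 CPM added to both sides. At least 3 of its markers had to reach 1.5-fold, the mean had to be above 0, and no other class could have more markers among the 10 leading genes. A cluster whose median UMI count in a library, multiplied by 3, stayed below that of the library's cells was left unnamed if none of its markers was among the leading genes. Leading genes were ranked by fold among genes with at least 50 UMIs in the cluster and a UMI in at least 10% of its cells. This naming rule was set after the clusters had been seen and was revised 2 times. A first form called cluster 7 fibroblast from 2 markers, and a second form called cluster 8 quiescent from a negative mean. The effects of both forms are among the alternatives. Names are used in the sense of "like": a quiescent cell here is a cell of a cluster with markers shared by quiescent neural stem cells and astrocytes, which were not separated.

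Expression of a class was the sum of UMIs over its cells, scaled to a common total (CPM), with exact 95% Poisson intervals. Shares of cells have exact 95% Clopper-Pearson intervals. A count of 0 allows up to 3 counts. With 1 library per age there was no replicate, so no test was made and no p-value is given, and all intervals cover counting error only. The 24 gene lists had 801 members in total, counting a gene once for each list that holds it. For each list, the median log2 ratio of CPM was taken over members with at least 20 UMIs on both sides together. A member at 0 on one side was set to 3 counts there, which makes its ratio a bound. Each median has a binomial order-statistic interval over its members and a percentile among 10000 random lists of the same size, drawn from the 100 genes nearest in mean expression. Genes are not replicates, so both describe these libraries only. Classes with at least 50 cells in both libraries were compared between libraries. A cell was called cycling when it had at least 3 UMIs of the S phase and G2 and M phase lists together after thinning to 2000 UMIs. Shallower cells were left out.

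Genes named between libraries in the quiescent class were the 12 with the highest and the 12 with the lowest ratio. They needed at least 50 UMIs in 1 library and at least 4 in the other, intervals that did not overlap, and the same direction in every cluster of the class with at least 30 cells in both libraries (3 clusters). Markers of oligodendrocytes, neurons, erythroid cells and choroid plexus were counted apart as possible free RNA. For each list, the rule named the 2 members with the highest and the 2 with the lowest ratio among those with at least 50 UMIs on 1 side. Between classes the ratio was the smaller of both libraries, with the same direction in both, and not every member so named is printed. Sfrp5, Slc1a3, Egfr, Dcx, Gfap and Mki67 were always given, and results for some other genes that these rules name are not reported here. Gene positions are from GENCODE M21 on GRCm38, matched by gene identifier for 38 of 38 genes. No coordinates were given with the counts.

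The lists, markers, cell filters, main clustering settings, cycling threshold and the rule for named genes were chosen before the data were examined. Remaining details, such as the graph weighting by shared neighbours, the expected doublet rate and the pool for random lists, were fixed later. Alternatives were other cell filters, clustering resolutions of 0.5 and 2, 15 principal components, list members allowed in clustering, doublets kept, TMM scaling, scaling without ribosomal, mitochondrial and the 20 most abundant genes, other UMI minimums, thinning, the largest cluster alone, and other cycling thresholds. Alternatives chosen after the data had been seen were the earlier naming rules, a mean within clusters, leaving out cluster 10, and cluster 7 alone as the quiescent side.

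The calculation of ratios and lists was tested on simulated data of 3 clusters, comparing library 1 with library 2. Gene means were those of all barcodes, and depths were fixed shares of each library's UMIs, not the depths of the quiescent class. More genes met the UMI minimums than in the quiescent class (8983 against 7188), so the rates found can be too favourable for it. Over 8983 genes, the conditions for a named gene were met by 36 of 55 genes changed 1.5-fold (65.5%), 57 of 61 changed 2-fold (93.4%) and 64 of 64 changed 4-fold. They were also met by 42 of 8787 unchanged genes (0.478%). In a simulated shift of the interferon list by a log2 of 1 over 12040 genes, the median found was 1.03 at percentile 100, and 0 of 23 other lists left the central 95% of random lists. Simulated counts carried counting error only: both libraries and all 3 clusters shared the same gene means apart from the set changes. The low rates for unchanged genes and lists follow from this, and they leave out differences between pools, sorts or library preparations.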

Results

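The data were single-cell transcriptomes of GLAST-sorted cells from the subventricular zone of mice aged 2 months and 22 months, with 1 library per age. The design asked how neural stem cells and their progeny differ between young and old animals. The cells carried a library number that no label tied to an age, so library 1 and library 2 are compared without naming an age. Totals were 10440891 UMIs over 1849 barcodes in library 1 and 13330251 UMIs over 2088 barcodes in library 2. Single barcodes ranged from 1440 to 56406 UMIs in library 1 and from 1510 to 24313 in library 2. For each library 8000 sort events had been loaded. There were no replicates, and intervals cover counting error only.

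Quiescent cells, with stem cell and astrocyte markers, took a larger share of library 1 than of library 2. They made up 41.9% of library 1 (765 of 1825 cells, interval 39.6 to 44.2%) and 30.4% of library 2 (628 of 2064, 28.4 to 32.5%). Activated stem cells or transit amplifying progenitors made up 15.7% of library 1 (14.1 to 17.5%) and 23.6% of library 2 (21.8 to 25.5%). Neuroblasts, the migrating neuronal precursors, made up 20.3% (18.5 to 22.2%) and 24.7% (22.8 to 26.6%). Oligodendrocytes made up 5.53% of library 1 (4.53 to 6.68%) but 0.436% of library 2 (9 cells, upper limit 0.826%), although the sort excluded O4, so the sort can set this share.

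Oligodendrocyte precursors numbered 16 cells in library 1 and 31 in library 2. Ependymal cells, which line the ventricle, made up 0.164% and 0.630%. Microglia numbered 2 and 4 cells. No endothelial cell was found among the 1825 cells of library 1, which allows a share of up to 0.164%, against 4 cells in library 2. Unnamed clusters held 15.4% of library 1 (13.8 to 17.1%) and 18.3% of library 2 (16.7 to 20.1%). Within the quiescent class, cluster 0 held 525 of the 765 cells of library 1 and 299 of the 628 of library 2. Cluster 10, with Gfap, Urah and Thbs4 among its leading genes, held 9 and 131 cells, and a cluster mostly of 1 library may be that library and not a cell type. This also holds for cluster 12, the oligodendrocytes. The chemokine gene Cxcl14 was among the leading genes of cluster 0, and the lysosomal glycoprotein gene Cd68 among those of cluster 1, an activated cluster. With the 26 marked doublets kept, clusters split differently and the activated class shrank to 105 cells (5.71%) of library 1 and 218 (10.5%) of library 2. With at least 1000 genes and at most 5% mitochondrial, activated cells made up 7.48% and 13.1%, and quiescent cells 29.0% and 17.1%, the latter below the 25.9% of neuroblasts in library 2. At resolution 2, activated cells made up 22.0% and 34.3%, more than the 30.7% of quiescent cells in library 2. The order of the classes by size in library 2 therefore depended on these settings, while the direction of the difference between libraries did not for quiescent cells, activated cells, neuroblasts and oligodendrocytes, the classes for which it was computed.

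**Figure D1:**
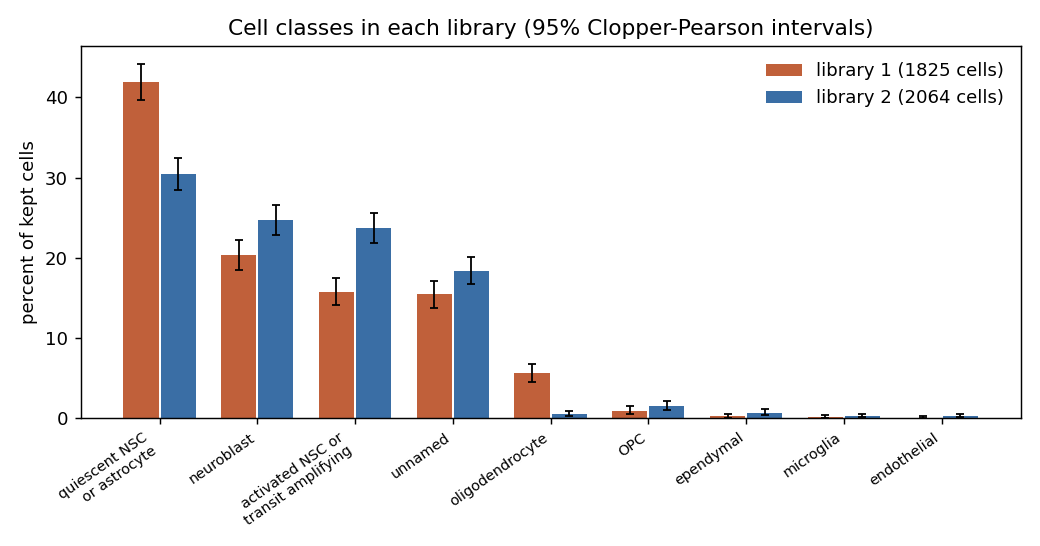
Share of kept cells in each class, in percent, for library 1 (1825 cells) and library 2 (2064 cells), with 95% Clopper-Pearson intervals as error bars. Quiescent cells and oligodendrocytes had the higher share in library 1 (41.9% and 5.53%), and activated cells in library 2 (23.6%).

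Marker genes of the lineage differed between the classes in both libraries. Slc1a3, Dcx, Egfr and Gfap were among the markers that named the clusters, so their differences between classes follow in part from the naming. Slc1a3, which encodes GLAST, stood at 2422 CPM in quiescent cells of library 1 and 2295 CPM in library 2, against 464 and 540 CPM in activated cells and 211 and 210 CPM in neuroblasts. Dcx, a microtubule-associated protein of migrating neuroblasts, reached 526 and 431 CPM in neuroblasts and 11.5 and 19.2 CPM in quiescent cells. Egfr, the growth factor receptor that marks activated stem cells, was higher in library 1 in the quiescent class (104 against 67.3 CPM, intervals 92.3 to 116 and 57.5 to 78.3) and in the activated class (227 against 137 CPM, 211 to 245 and 126 to 148). Gfap, the astrocyte intermediate filament, was lower in quiescent cells of library 1 (45.2 CPM, 37.9 to 53.5) than of library 2 (225 CPM, 206 to 244), and it was a leading gene of cluster 10, which came nearly all from library 2. Sfrp5, a secreted Wnt antagonist, stood at 15.5 CPM (11.4 to 20.7) in quiescent cells of library 1 and 12.4 CPM (8.44 to 17.6) in library 2, so no difference was detectable at this depth. In the activated class it had 0 UMIs in library 1 and 5 in library 2.

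Slc1a3, the gene of the antigen sorted for, was found in most kept cells but not at the same level in every class. A UMI of Slc1a3 was found in 82.8% of kept cells of library 1 (81.0 to 84.6%) and 83.5% of library 2 (81.8 to 85.1%), at median depths of 4442 and 5779.5 UMIs. The share was 99.2% and 99.4% in quiescent cells. In oligodendrocytes, at median depths of 4228 and 5119 UMIs, it was 48.5% (38.4 to 58.7%) in library 1 and 77.8% (40.0 to 97.2%) of 9 cells in library 2. The neuroblast shares of 41.1% and 51.9% were no higher than these. Oligodendrocytes passed the same sort for GLAST, so they are not a reference free of Slc1a3. How much of the neuroblast shares is background was not tested. Ptprc, which encodes CD45, was found in 2 cells of each library, all of them microglia.

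Genes of the interferon response and of antigen presentation were higher in quiescent cells of library 1 than of library 2. Of 33 measured interferon genes 30 were higher in library 1, 26 of them at least 1.5-fold, with a median log2 ratio of 1.14 (0.84 to 1.59) at percentile 100 of matched random lists. Ifit3b, an interferon-induced tetratricopeptide repeat gene, stood at 31.7 against 6.01 CPM, and Bst2, which tethers budding virions, at 35.7 against 8.01 CPM. Ifitm2, a membrane protein that restricts viral entry, went the other way and was 2.71-fold higher in library 2. Of 13 measured MHC class I and antigen presentation genes 11 were higher in library 1, with a median of 0.76 (0.36 to 1.54) at percentile 100. Psmb8, an immunoproteasome subunit, stood at 17.9 against 2.00 CPM and B2m, the MHC class I light chain, at 173 against 89.3 CPM, while Tapbp stood at 55.6 against 59.7 CPM.

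Glycolysis and fatty acid oxidation genes were also higher in quiescent cells of library 1. Glycolysis genes had a median log2 ratio of 0.40 (0.29 to 0.47), with 19 of 20 higher and Pfkp, a phosphofructokinase, 2.24-fold higher. Fatty acid oxidation genes had a median of 0.31 (0.20 to 0.43), with 25 of 27 higher. Among them Acsbg1, an acyl-CoA synthetase, and Cpt1a, which admits fatty acids to mitochondria, were both 1.61-fold higher. Both lists lay at percentile 100. Proteasome genes had a median of 0.11 (0.03 to 0.14) at percentile 98.3, with 28 of 37 higher. Some of them, such as Psmb8, are also in the antigen presentation list. With at least 1000 genes and at most 5% mitochondrial, the proteasome median was 0.045 and that of fatty acid oxidation 0.20. Wnt antagonists had a median of 0.32 over 5 members, 4 of them higher, while Sfrp1 was 2.52-fold higher in library 2. With at least 1000 genes and at most 5% mitochondrial, the Wnt antagonist median turned to -0.30, so its direction is not settled.

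Cell cycle, ribosomal and sterol genes were lower in quiescent cells of library 1. All 29 measured G2 and M phase genes were lower, 28 of them at least 1.5-fold, with a median log2 ratio of -1.06 (-1.25 to -0.75) at percentile 0. Cdk1, the mitotic kinase, stood at 6.41 against 20.0 CPM. Of 32 S phase genes 27 were lower, with a median of -0.39 (-0.72 to -0.31), and Rrm2, a ribonucleotide reductase subunit, stood at 23.6 against 58.5 CPM. Mki67 stood at 10.5 and 20.8 CPM in quiescent cells, while oligodendrocytes, which do not divide, held 24.7 CPM (12.8 to 43.2) in library 1, from 4 cells. Levels this low can thus rest on a few cells, and whether they come from other cells was not tested. All 77 ribosomal protein genes were lower, 1 of them at least 1.5-fold, with a median of -0.31 (-0.33 to -0.29), or -0.51 with at least 1000 genes and at most 5% mitochondrial. Fatty acid and cholesterol synthesis genes had a median of -0.31 (-0.50 to -0.13), with 24 of 29 lower. These 3 lists lay at percentile 0. Within cluster 0 alone, the median was -0.12 for S phase, -0.13 for ribosomal proteins, 0.19 for the proteasome and -0.53 for fatty acid and cholesterol synthesis.

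The other lists had intervals that included 0 in the quiescent class. The proneural and neuronal differentiation list had a median log2 ratio of -0.40 at percentile 0.090, with 10 of 13 members lower in library 1, and -0.13 within cluster 0 alone. Pax6, a transcription factor of neural progenitors, was 1.74-fold higher in library 2. Inflammation and reactive glia genes had a median of 0.017 with 8 of 15 higher, although C4b, a complement component, was 2.08-fold higher in library 1. Immediate early and dissociation response genes had a median of 0.12, CDK inhibitors 0.11, the Notch pathway 0.13, the BMP and TGF-beta pathway 0.12, Wnt receptors and targets 0.15, and lysosome and autophagy 0.089. With at least 1000 genes and at most 5% mitochondrial, CDK inhibitors turned to -0.14, and Wnt receptors and targets stood at 0.30 and lysosome and autophagy at 0.18. Translation factors had a median of -0.035, nuclear oxidative phosphorylation genes -0.034, the mitochondrial genome -0.064, DNA damage and oxidative stress -0.044, extracellular matrix and adhesion -0.033, and stem cell transcription factors -0.057. Within cluster 0 alone, the mitochondrial genome stood at -0.32, nuclear oxidative phosphorylation at -0.14, extracellular matrix and adhesion at -0.18 and immediate early genes at 0.42, so medians near 0 for the class do not exclude differences in its clusters. The median over all 11080 genes was 0.0055.

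**Figure D2:**
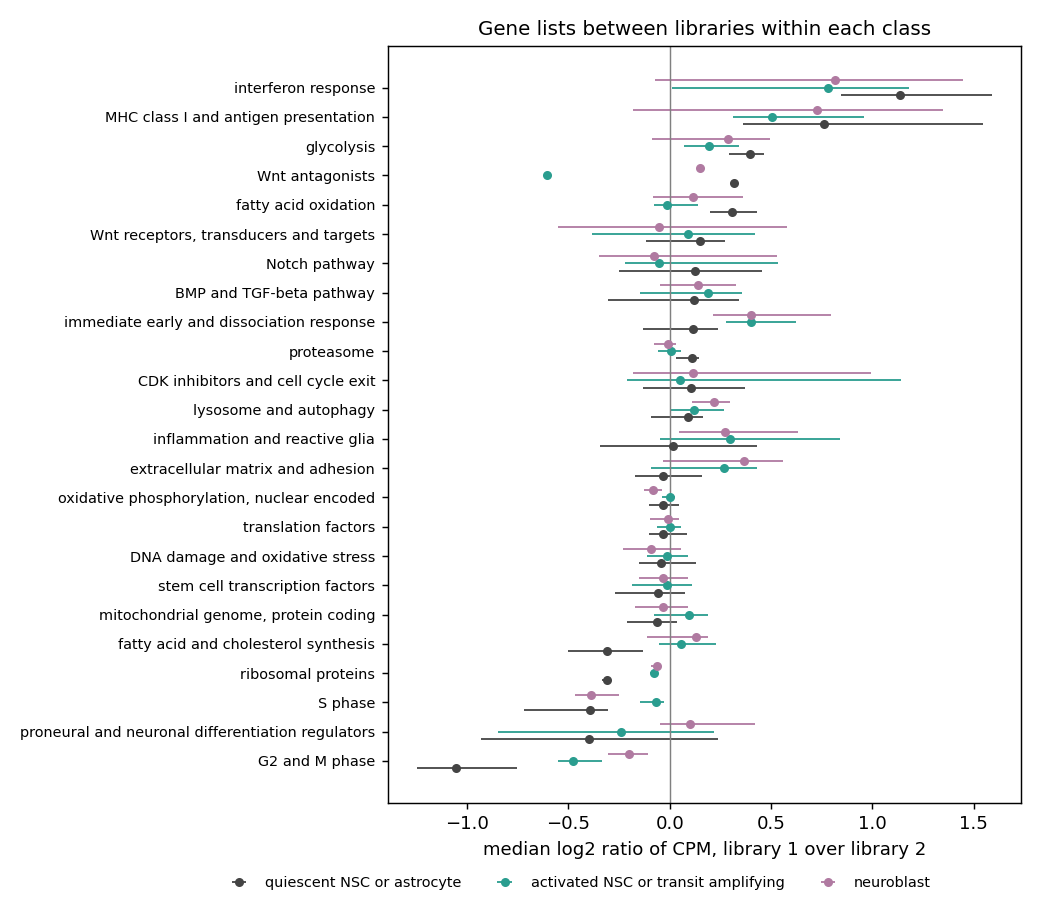
Median log2 ratio of CPM (x axis, library 1 over library 2) for each gene list in quiescent cells, activated cells and neuroblasts. Points are medians and lines their 95% order-statistic intervals over list members, drawn where there were enough members, with the interferon list highest (1.14) and the G2 and M phase list lowest (-1.06) in quiescent cells.

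Single genes with the largest ratios in quiescent cells were drawn from 7188 genes with at least 50 UMIs in 1 library. The highest toward library 1 were Psmb8 (chromosome 17, 34197721 to 34201454) and Zc3hav1, an antiviral zinc finger protein (chromosome 6, 38305286 to 38354603), each at 17.9 CPM (13.4 to 23.4) against 2.00 CPM (0.650 to 4.67), or 8.92-fold higher. Rspo3, a secreted Wnt agonist on chromosome 10 (29452416 to 29535867), stood at 32.0 against 5.21 CPM and was also a leading gene of cluster 7. Wls, which carries Wnt proteins to the cell surface, stood at 155 against 43.7 CPM. The others were Ifit3b, Gpd1, Bst2, Ifit3, Npl, Irgm1, Car14 and Chrdl1, between 3.72-fold and 5.28-fold higher. Ifit3 and Ifit3b are close paralogs, and how reads were shared between them is uncertain.

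Toward library 2, the largest ratio was that of the histone gene Hist1h2ap (chromosome 13, 21833026 to 21833507), at 88.5 CPM (lower limit 77.2) against 10.8 CPM (upper limit 15.2), or 8.20-fold higher. Its log2 ratio was -1.50 in cluster 0, -0.20 in cluster 7 and -4.09 in cluster 9, so the class value did not describe each cluster. Histone copies are near-identical, so its count is uncertain, and it was a leading gene of cluster 2, a cycling cluster. Nes, the intermediate filament nestin of neural progenitors (chromosome 3, 87971078 to 87980451), was 4.89-fold higher in library 2, at 28.0 against 5.73 CPM. The cilium-related genes Cfap126 and Mns1 were 6.18-fold and 3.65-fold higher. Ependymal cells also took a larger share of library 2 (0.630% against 0.164%). Ependymal markers were not counted apart as possible free RNA, so whether free RNA adds to these ratios was not tested. Anxa2, an annexin, was 4.09-fold higher. Urah, a leading gene of cluster 10, was 6.02-fold higher over the class with log2 ratios of -0.028 in cluster 0, -1.86 in cluster 7 and -1.13 in cluster 9, and Dleu7, Hist3h2ba, Mlf1, Gm9844, Slc35f1 and Cnih2 were between 3.51-fold and 4.92-fold higher. All positions are on GRCm38, and all these genes are annotated as protein coding.

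Oligodendrocyte transcripts were found in quiescent cells and were higher in library 1, where oligodendrocytes took the larger share. The ratio ran from 1.33-fold for Cnp to 12.2-fold for Cldn11. These markers are read as possible free RNA and not as expression.

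In the activated class, interferon genes were higher in library 1 for 16 of 21 measured members, with a median log2 ratio of 0.78 (0.01 to 1.18). The MHC class I list had a median of 0.50 (0.31 to 0.96), with B2m 1.94-fold and H2-D1 1.90-fold higher. Immediate early genes had a median of 0.40 (0.28 to 0.62), with 29 of 33 higher and Egr2 1.98-fold higher, while all 36 G2 and M phase genes were lower, with a median of -0.48 (-0.55 to -0.33). With marked doublets kept, the activated class held 105 and 218 cells and the interferon median was -0.068, and with at least 1000 genes and at most 5% mitochondrial it was 0.19. Cdc20 was 2.05-fold, Ube2c 2.01-fold and Bub1 1.08-fold higher in library 2.

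In neuroblasts, 11 of 14 interferon genes were higher in library 1, with a median log2 ratio of 0.82 (-0.07 to 1.45), and Ifi27 stood at 123 against 51.7 CPM. The MHC class I median was 0.73 over 7 members. Immediate early genes were higher for 28 of 29 members, with a median of 0.40 (0.21 to 0.79), and Nr4a1, an orphan nuclear receptor induced by stimulation, was 2.62-fold higher. S phase genes had a median of -0.39 (-0.47 to -0.25) and G2 and M phase genes -0.20 (-0.30 to -0.11), which were -0.14 and -0.82 in the largest neuroblast cluster alone. After thinning the G2 and M phase median was -0.33. By cluster, the interferon median was above 0 in all 8 clusters where it could be measured, from 0.06 in cluster 5 to 1.52 in cluster 8.

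**Figure D3:**
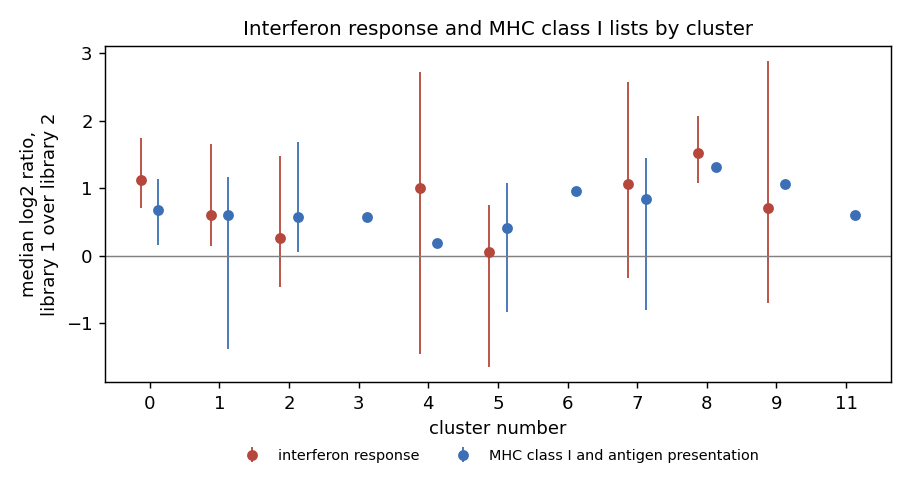
Median log2 ratio of CPM (y axis, library 1 over library 2) of the interferon response and MHC class I lists in each cluster with enough cells and members (x axis, cluster number). Lines are 95% order-statistic intervals over members, and the interferon median ran from 0.06 in cluster 5 to 1.52 in cluster 8.

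Activated cells had higher CPM of cell cycle and ribosomal genes than quiescent cells in both libraries. All 36 G2 and M phase genes and all 33 S phase genes were higher in both, with median log2 ratios of 3.66 (3.11 to 3.95) and 2.94 (2.66 to 3.11) for G2 and M, and 2.40 (2.20 to 2.70) and 2.08 (1.97 to 2.32) for S phase, in library 1 and library 2. Top2a, the DNA topoisomerase of dividing cells, was 17.6-fold and 11.7-fold higher. All 77 ribosomal protein genes were higher in both, 76 of them at least 1.5-fold in both, with medians of 1.27 (1.20 to 1.34) and 1.06 (0.99 to 1.10). Rps26 was 4.00-fold and 3.05-fold higher. Translation factors had medians of 0.64 and 0.65, with 49 of 61 higher in both. The proneural list had medians of 1.74 and 1.26, with 11 of 13 higher in both, and Sox4, a transcription factor of neuronal commitment, was 7.81-fold and 6.30-fold higher.

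Lipid oxidation, glycolysis, lysosome and matrix genes had lower CPM in activated than in quiescent cells. CPM is a share of UMIs, and activated cells were deeper. Their median depths were 9869 and 9071 UMIs, against 3563 and 3595.5 in quiescent cells of library 1 and library 2. A lower CPM here therefore need not mean fewer transcripts per cell. All 26 fatty acid oxidation genes were lower in both libraries, 23 of them at least 1.5-fold in both, with medians of -1.96 (-2.82 to -1.50) and -1.69 (-2.07 to -1.11). Acsbg1 was 12.4-fold and 10.4-fold lower. Counts of members here and for neuroblasts are those with the same direction in both libraries, out of members measured in both. Glycolysis genes were lower for 19 of 20 members, with medians of -1.59 and -1.48, and the exception was Hk2, a hexokinase, which was 1.90-fold and 2.32-fold higher. Lysosome and autophagy genes were lower for 27 of 31 members, with medians of -1.73 and -1.41, and the protease gene Ctsl was 9.70-fold and 9.73-fold lower. Extracellular matrix genes were lower for 16 of 19 members, with medians of -1.87 and -1.88, and Sparc, a matrix glycoprotein, was 27.8-fold and 35.7-fold lower. Interferon genes were lower for 17 of 22 members, with medians of -1.30 (-2.02 to -0.99) and -0.95 (-1.90 to -0.31), the first of which was -2.03 with marked doublets kept. MHC class I genes were lower for 8 of 10, with medians of -1.58 (-2.55 to -1.14) and -1.42 (-2.72 to 0.21), and H2-K1 was 6.75-fold and 6.59-fold lower. Wnt antagonists had medians of -3.76 and -1.69, the first of which was -1.87 after thinning to equal depth, while Draxin among them was 4.27-fold and 5.90-fold higher.

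All medians named for activated over quiescent cells lay outside the central 95% of matched random lists, although the intervals of Wnt antagonists (-3.49 to 2.56) and of MHC class I genes (-2.72 to 0.21) in library 2 included 0. Classes were formed from genes that vary together with list members, so part of these differences follows from how the classes were formed. TMM scaling moved the median of all genes from -0.019 to 0.10 in library 2, and no median named here changed sign.

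**Figure D4:**
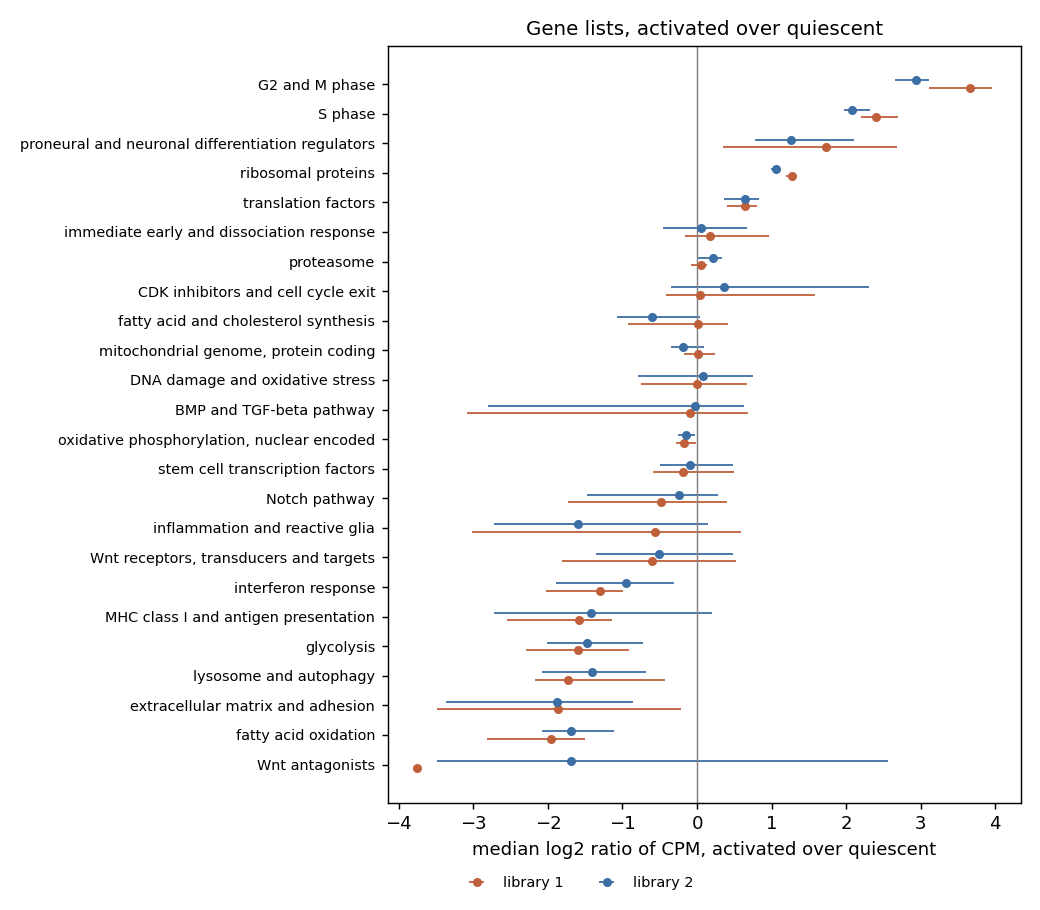
Median log2 ratio of CPM (x axis, activated over quiescent cells) of each gene list, for library 1 and library 2. Points are medians and lines 95% order-statistic intervals over members, with cell cycle lists highest (3.66 for G2 and M phase in library 1) and fatty acid oxidation among the lowest (-1.96).

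Neuroblasts had lower CPM of immediate early and Notch genes than activated cells. Their median depths of 3595.5 and 5262 UMIs were below the 9869 and 9071 of activated cells. A higher CPM in neuroblasts therefore need not mean more transcripts per cell. Immediate early genes were lower for 27 of 31 members in both libraries, with median log2 ratios of -1.67 (-1.96 to -1.09) and -1.44 (-2.30 to -0.67). Egr2, a zinc finger transcription factor, was 8.76-fold and 9.37-fold lower, while Btg1, an antiproliferative gene, was 3.14-fold and 2.70-fold higher. Notch pathway genes were lower for 13 of 16 members, with medians of -0.99 (-2.25 to -0.12) and -0.89 (-1.74 to -0.43), and the Notch target Hes1 was 11.5-fold and 21.4-fold lower. The proneural list had medians of 1.34 and 0.82, with 11 of 14 higher, and Celf4, an RNA-binding protein of neurons, was 21.8-fold and 12.3-fold higher. Cdkn1b, which encodes the cell cycle inhibitor p27, was 2.95-fold and 2.62-fold higher, while Cdkn1a, which encodes p21, was 3.35-fold and 2.78-fold lower.

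Fatty acid and cholesterol synthesis genes were lower in neuroblasts for 22 of 29 members, with medians of -0.59 and -0.57. Glycolysis genes had medians of -0.54 (-0.29 with list members in clustering) and -0.58, and Hk2 was 20.7-fold and 8.15-fold lower. Ribosomal protein genes were lower for 69 of 77 members, with medians of -0.27 (-0.32 to -0.21) and -0.26 (-0.29 to -0.22), which were -0.063 and -0.11 with marked doublets kept. Inflammation genes had medians of -0.78 and -1.03. S phase genes were lower for 32 of 33 members, with medians of -0.72 and -0.42 (-1.12 in library 1 with marked doublets kept and -0.82 in library 2 after thinning to equal depth), and Mcm2, a subunit of the replicative helicase, was 2.42-fold and 2.94-fold lower. G2 and M phase genes had medians of 0.44 and 0.18, which were -0.27 and -0.40 with marked doublets kept and 0.086 and -0.13 after thinning, so their direction is not settled.

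**Figure D5:**
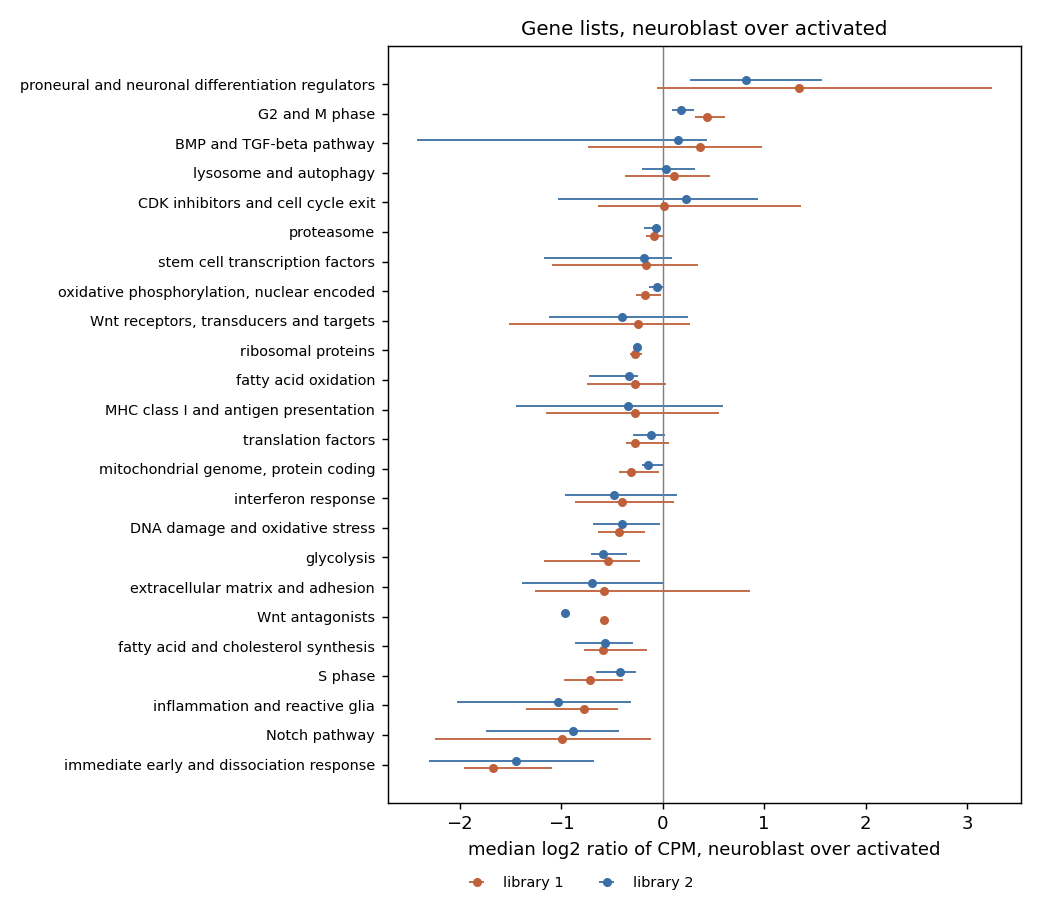
Median log2 ratio of CPM (x axis, neuroblasts over activated cells) of each gene list, for library 1 and library 2. Points are medians and lines 95% order-statistic intervals over members, with immediate early genes lowest (-1.67 and -1.44) and the proneural list highest (1.34 and 0.82).

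Nearly all activated cells passed the cycling threshold. After thinning to 2000 UMIs, 94.4% of activated cells of library 1 (91.0 to 96.8%) and 96.3% of library 2 (94.2 to 97.8%) had at least 3 cell cycle UMIs. Neuroblasts reached 70.3% (65.1 to 75.1%) and 83.8% (80.2 to 86.9%). The make-up of this class differed between libraries. Cluster 4, at 100% in both libraries, held 95 of the 370 neuroblasts of library 1 and 202 of the 509 of library 2. Cluster 3, at 50.0% and 61.2%, held 169 and 157. Quiescent cells reached 33.3% (29.8 to 37.0%) and 53.1% (49.0 to 57.2%), no more than oligodendrocytes, which reached 37.2% (27.5 to 47.8%) of 94 cells and 62.5% (24.5 to 91.5%) of 8 cells. The comparison in library 2 rests on 8 oligodendrocytes. Within the quiescent class, cluster 9 reached 55.0% (45.2 to 64.6%) and 73.2% (61.4 to 83.1%), against 27.7% (23.7 to 32.0%) and 43.1% (37.2 to 49.2%) in cluster 0, so a single background level did not describe the class. How much of these shares is background was not settled. Thinning left out 80 and 35 quiescent cells, 2 and 0 activated cells and 30 and 16 neuroblasts. Unthinned shares were 60.3% and 81.8% in quiescent cells, 100% in activated cells of both libraries, and 81.4% and 92.3% in neuroblasts. With a threshold of 5 UMIs after thinning, they were 8.03% and 15.7% in quiescent cells, 86.0% and 90.2% in activated cells, and 46.2% and 62.5% in neuroblasts.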

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

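The tests of free RNA, of cluster make-up, of the leading genes of cluster 10 and of the dissociation response were chosen only after the result was seen. The tests of ependymal and of microglial RNA were set before their values were computed. With 1 library per age, no library was tested against others of its group.

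Unnamed clusters stood out because they lie outside the classes compared and exceed the 0.164% and 0.145% that a count of 0 allows in library 1 and library 2. Cluster 5 held 6.14% of library 1 and 7.99% of library 2. Cluster 8 held 7.40% and 4.17%, cluster 11 held 1.75% and 4.89%, and cluster 14 held 1.26% of library 2.

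Interferon response and MHC class I genes were higher in library 1 in quiescent cells. Free RNA reaching every class alike was argued against: the excess of library 1 in summed CPM was 0.313 times as large in neuroblasts as in quiescent cells (0.255 to 0.375). A different make-up of clusters was also argued against, since the median log2 ratio of the interferon list within clusters 0, 7 and 9 was 1.22 (0.79 to 1.49). The age of the mice may underlie the difference, but so might any difference between the pools, the sorts or the library preparations, and these stay open and untested with 1 library per age. Which library came from which age is not known, so the direction with age is open as well.

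Cluster 10, with Gfap, Urah and Thbs4 among its leading genes, came nearly all from library 2. Ependymal doublets, or ependymal RNA near its ependymal level, were argued against. The 4 ependymal genes Tmem212, Ccdc153, Tm4sf1 and Rarres2 reached 1.90% (1.46 to 2.38%) of their ependymal level in its library 2 cells. A small amount of free ependymal RNA could give such a value and is not excluded, since no other quiescent cluster was used as a baseline. A shift of its 10 leading genes in every cell of library 2 could place such cells apart. In clusters 0, 7 and 9 these genes were higher in library 2 by a median log2 ratio of 0.64 (-0.53 to 1.16), with single values from -1.06 to 3.98. The interval lay below the median of 2 set for this explanation, but its upper end passed the limit set against it. These values therefore do not decide it. A cell state tied to the age of either pool stays open and untested.

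Cluster 8 had chemokine and stress genes among its leading genes, such as Cxcl10, Cxcl1, Atf3, Maff and Nr4a1. Microglia mixed into it were argued against, since C1qa, C1qb, Ctss and Tyrobp reached 0.0117% (0 to 0.0271%) of their microglial level, and the sort excluded CD45. A response to tissue dissociation is a possible explanation: the immediate early list, without its 3 members among the 10 leading genes, was above clusters 9 and 1 by median log2 ratios from 1.32 (0.96 to 1.81) to 1.85. The lower bound of the smallest falls just under the value of 1 set for it. Members of the same list led the cluster, so a high median was likely and cannot tell dissociation from another stimulus. The explanation therefore stays open. No biological explanation was tested for this cluster, since the design gives none.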

How the results depend on the processing

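The alternatives that use the earlier naming rules, a mean within clusters, cluster 7 alone or the class without cluster 10 were chosen only after the data had been seen. No paired analysis was possible because there was 1 library per age, so the groups share fewer than 2 replicate numbers, and no result came from a test. Depth limits lists with few UMIs, such as interferon genes in neuroblasts, and shares of rare classes.

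Class differences between libraries stayed within their counting intervals under 29 of 34 alternatives, and none changed sign. The quiescent difference of 11.5 percentage points was 14.7 with cluster 8 counted as quiescent. The activated difference of -7.92 was -11.1 at resolution 0.5, -12.2 at resolution 2, -12.5 with list members in clustering and -4.80 with doublets kept. Shares within a library were less stable, and 29 of 68 values moved. With at least 1000 genes and at most 5% mitochondrial, library 1 and library 2 had 7.48% and 13.1% activated and 29.0% and 17.1% quiescent cells, and at resolution 2 they had 22.0% and 34.3% activated cells. A list median is called reversed where its main interval excluded 0 and the sign differed, and one whose interval included 0, or that had none, can change sign and count as moved or as unchanged. For 13 leading list results between libraries, 123 of 137 values stayed within their interval, 13 moved and 1 reversed. For the other 59 list results, 492 of 529 stayed, 34 moved and 3 reversed. In quiescent cells the interferon median of 1.14 ran from 0.94 to 1.37 and stayed within its interval under all alternatives run. Within the largest cluster, S phase was -0.12, ribosomal proteins -0.13, fatty acid and cholesterol synthesis -0.53 and the proteasome 0.19. G2 and M phase was -0.73 with doublets kept and -0.73 with at least 1000 genes and at most 5% mitochondrial. Ribosomal proteins were -0.51 under that filter, -0.36 after thinning, -0.34 with doublets kept, -0.24 as a mean within clusters 0, 7 and 9, -0.23 with cluster 8 and -0.28 without cluster 10. Glycolysis was 0.28 as a mean within clusters. In activated cells with doublets kept, interferon reversed to -0.068 and S phase to 0.12. S phase also reversed to 0.15 with at least 1000 genes and at most 5% mitochondrial, and lysosome and autophagy to -0.0031 after thinning. In quiescent cells under that joint filter, Wnt antagonists turned from 0.32 to -0.30 and CDK inhibitors from 0.11 to -0.14. Other moves across 0 were fatty acid oxidation in activated cells (-0.011 to 0.27 after thinning), and in neuroblasts fatty acid and cholesterol synthesis (0.13 to -0.12 in the largest cluster) and the proteasome (-0.010 to 0.053 after thinning and 0.076 in the largest cluster).

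For 35 leading list results between classes, 258 of 294 values stayed within their interval, 33 moved and 3 reversed. For the other 61, 456 of 472 stayed, 15 moved and 1 reversed. Activated over quiescent, with doublets kept, S phase was 3.34 in library 1 and 2.86 in library 2, G2 and M phase 4.66 and 4.03, interferon -2.03 in library 1 and ribosomal proteins 1.15 in library 2. With cluster 7 alone as the quiescent side, S phase was 2.79 and 2.5, ribosomal proteins 1.13 and 0.95, G2 and M phase 3.26 in library 2, and oxidative phosphorylation in library 1 reversed from -0.17 to 0.035. With list members in clustering, G2 and M phase was 4.04 and 3.40, ribosomal proteins 1.15 in library 1 and S phase 2.38 in library 2. After thinning, ribosomal proteins were 1.48 and 1.20 and S phase 2.35 in library 2. With cluster 8 counted as quiescent, ribosomal proteins were 0.99 and 0.85 and S phase 1.90 in library 2. TMM scaling gave ribosomal proteins 1.18 in library 2. Wnt antagonists in library 1 went from -3.76 to -1.87 after thinning and to -2.96 with at least 100 UMIs. Immediate early genes in library 1 turned from 0.17 to -0.35 with list members in clustering, -0.62 with cluster 8 counted as quiescent and -0.71 against cluster 7 alone. Neuroblast over activated, with doublets kept, G2 and M phase reversed to -0.27 and -0.40, S phase was -1.12 in library 1, and ribosomal proteins were -0.063 and -0.11. After thinning, S phase was -1.06 and -0.82, G2 and M phase 0.086 in library 1 and reversed to -0.13 in library 2, and glycolysis -0.85 in library 2. With list members in clustering, library 1 gave S phase -1.01, G2 and M phase 0.034 and ribosomal proteins -0.19, and Wnt antagonists turned from -0.58 to 0.035. Without the most abundant genes, ribosomal proteins were -0.30 in library 2.

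Cycling shares moved with the threshold and depth in 27 of 34 values, given for library 1 and library 2. Quiescent shares were 60.3% and 81.8% unthinned, 10.1% and 20.9% after thinning to 1000 UMIs, 58.1% and 78.4% at 2 UMIs, and 8.03% and 15.7% at 5 UMIs. In library 1 they were 28.2% with doublets kept and 37.7% with cluster 8. Activated shares were 100% and 100% unthinned and with doublets kept, 81.2% and 86.5% at 1000 UMIs, 86.0% and 90.2% at 5 UMIs, and 99.0% in library 2 at 2 UMIs. Neuroblast shares were 81.4% and 92.3% unthinned, 46.0% and 61.3% at 1000 UMIs, 81.5% and 92.7% at 2 UMIs, and 46.2% and 62.5% at 5 UMIs. A lower threshold or deeper cells admit more cells by construction. All 12 alternative values for the sort genes stayed within their intervals. With doublets kept, clusters around the activated class split differently and fewer were named activated. For every other value that moved or reversed, the cause was not tested.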

Other observations

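The values here were chosen after the data had been seen, and no hypothesis was tested on them.

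The quiescent class held clusters with different programmes. Cluster 9, which had Notum, Axin2 and Sp5, genes of Wnt feedback, among its 10 leading genes, had more ribosomal protein transcript than cluster 0 for 77 of 77 genes, with median log2 ratios of 1.48 (1.38 to 1.57) in library 1 and 1.64 (1.53 to 1.68) in library 2. S phase genes were also higher in cluster 9 for 28 of 28 and 26 of 26 genes, with medians of 1.5 (1.28 to 2.28) in library 1 and 2.30 (1.91 to 2.69) in library 2, while extracellular matrix genes were lower, by medians of -0.68 and -1.08. Cluster 7, led by Rspo3, Adamts18 and Ecel1, had more immediate early transcript than cluster 0 for 31 of 31 genes in both libraries, with medians of 2.40 (1.85 to 2.92) and 2.27 (1.48 to 3.09). Its ribosomal protein medians over cluster 0 were 0.76 and 0.89. Nuclear oxidative phosphorylation genes were lower in cluster 7 than in cluster 0, by -0.21 and -0.32. Median depths in library 1 and library 2 were 6115 and 5763 UMIs in cluster 9 and 3935 and 3992 in cluster 7. In cluster 0 they were 3344 and 3258, so lower CPM in clusters 9 and 7 need not mean fewer transcripts per cell.

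Immediate early genes were close to equal between libraries in the quiescent class as a whole (0.12), but were higher in library 1 within cluster 0 (0.42, 25 of 29 genes) and cluster 7 (0.41, 25 of 32). In the unnamed cluster 8 the median was 0.39 (28 of 34 higher), and in cluster 9 it was -0.09 over 29 genes. Some genes differed the same way in all 3 lineage classes. Cdkn1a, which encodes the cell cycle inhibitor p21, was higher in library 1, by 2.46-fold in quiescent cells, 2.40-fold in activated cells and 1.99-fold in neuroblasts. Pax6, a transcription factor of neural progenitors, was higher in library 2, by 1.74-fold, 3.47-fold and 2.61-fold, and the Wnt antagonist Sfrp1 by 2.52-fold, 4.29-fold and 3.28-fold. Prox1, a homeobox factor of neuronal differentiation, was 1.95-fold higher in library 1 in both activated cells and neuroblasts.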
